A study of Rattus norvegicus with 12 samples.

How the data were processed

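The data are microarray measurements of total RNA from liver and renal cortex of 3 rats given trichloroethylene and 3 rats given corn oil. Per the labels' protocols, about 50 mg of each tissue was taken, RNA was isolated with Trizol and purified on RNeasy columns, biotin-labelled complementary RNA was made, and it was hybridised to GeneChip rat genome arrays, on which several short oligonucleotide probes form a probe set for a transcript. The authors deposited 1 table of log2 expression values, 31099 probe sets by 12 arrays, which has no missing values and reaches from a shared lowest value of 2.17 (5487 probe sets sit there on all arrays) to 16.5. That the scale is log2 was read from the range of the values. The packages affy and limma were used upstream, per the submitters' processing notes; their versions, the background correction, the normalization and the probe set summary are not given in the sources used here. The median of each array was 3.51 to 3.54 in liver and 3.88 to 3.96 in kidney. Besides the shared lowest value, 2420 probe sets had a repeated lowest value of their own on 3 or more arrays.

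Arrays were grouped by tissue and by the word in the sample title that marks treated or control rats, the treated being the TCE rats of the treatment protocol. Both tissues came from the same 6 rats; the labels do not say whether equal replicate numbers in liver and kidney mark the same rat, and the fit over both tissues treats the 12 arrays as independent. No 2 arrays held identical values. Probe sets were named from GEO's platform annotation: 20826 had 1 gene symbol (14217 genes), 436 several and 9780 none, and 57 control probe sets were left out of the tests. Of the singly named probe sets 20758 had a gene ID found in the current RefSeq gene table of rat assembly GRCr8, which changed 0 symbols. Probe sets with several symbols or none were not named.

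A gene was represented by the probe set with its 1 symbol and the highest mean over the 12 arrays, and was tested where its mean over the arrays of the fit exceeded the 40th percentile of all probe sets (2.447 log2 units in liver, 2.43 in kidney and 2.549 in the fits over both tissues). Where a named gene had further probe sets that pointed the other way, their values are given. The tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the deposited values without further normalization, two-sided, with Benjamini-Hochberg adjustment over all genes of a fit and a threshold of 0.05. The comparisons were TCE against control in liver (6 arrays), the same in kidney (6 arrays), the difference between these effects (12 arrays, 4 group means) and control liver against control kidney (6 arrays), all without covariates. SE is limma's moderated standard error, except in the following. For clock genes in phase minus genes in antiphase it comes from the SDs of the 3 arrays of each group. For the second podocyte list it is that of the median across genes. Gene lists, 41 in all and 20 of them cell type markers, were tested with limma's camera at its preset correlation of 0.01 where 5 or more members were measured, with the 72 list tests of both tissues adjusted together, and again with the correlation estimated per list. Erythroid and neutrophil markers had too few measured members for that test at the main filter. Members of a list were also adjusted over the list alone. Single values per array, such as control probe set ratios, were compared by exact permutation, for which 0.1 is the smallest p that 3 against 3 allows.

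The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule was as follows. With fewer than 10 genes past the threshold in a tissue, it named the 10 genes in each direction with the smallest p among those whose treated and control values did not overlap. It named preset enzymes of methionine and folate metabolism whatever their values. It named up to 4 members with the largest change of each list past its test or with a member past over the list alone (where none was past, the 4 with the smallest p), and up to 8 genes of the difference in effect. A few further names that the counts called for, such as Cox6a1, Cry2, Bhlhe40, Pfkl and Foxo1 among list members past over the list alone, and Uqcrc2 and Ndufb8 among the 57 genes, were chosen after their values were seen.

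Alternatives tried were no filter and a stricter one (60th percentile), all probe sets, the mean of a gene's probe sets, quantile normalization again, centring each array on its median, trend and robust variances, array weights, a replicate block, all 12 arrays in the fit of a tissue, thresholds of 0.1 and of 1.5-fold, and leaving out each array in turn. Chosen after seeing the data were the Gapdh 3' to 5' gap as a covariate, leaving out genes with a repeated value throughout a group, lists without cell type markers, camera on the difference of effects, and the lists and list members recomputed without each array. The procedures were tested on simulated data with the real genes' means and spreads and 200 genes changed by known folds: in liver (10552 genes, 6 arrays) 40.3%, 59.7% and 81.8% of genes changed 1.5-, 2- and 4-fold were called, in kidney (10563 genes, 6 arrays) 32.8%, 65.7% and 86.4%, in the difference of effects (10652 genes, 12 arrays) 13.4%, 56.7% and 78.8%, and between control tissues (10654 genes, 6 arrays) 25.4%, 61.2% and 89.4%. The shares called depend on how many genes are changed, since an adjusted threshold is easier to reach when many genes pass. In the real liver and kidney comparisons 0 genes passed, so these shares do not give the power there. A list shifted by 0.5 log2 units was recovered in both tissues with 0 other lists called. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls lists falsely where the genes of a list vary together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.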

Results

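Gene expression was measured in liver and renal cortex of male rats given trichloroethylene (TCE), a chlorinated solvent that is oxidised by hepatic Cyp2e1, among other enzymes. TCE was given by mouth for 3 days at 16 mg/kg per day in corn oil (5 ml/kg), and control rats received corn oil alone. The rats were killed 24 h after the last dose. There were 3 treated and 3 control rats, and liver and renal cortex of each group were hybridised to GeneChip rat genome arrays, giving 3 arrays in each of 4 groups and 12 in all. Each array holds log2 values for the same probe sets, of which 27.5% to 29.1% sat at the shared lowest value. The labels call the rats Wistar-derived and also name the strain F-344. Arrays of one group correlated with each other at 0.9928 to 0.997 across probe sets, and liver arrays with kidney arrays at 0.8502 to 0.8634. The number of arrays limits the precision of every value that follows.

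In liver, where the study asked how TCE acts on vitamin B12-dependent methionine salvage, the gene with the smallest p between treated and control rats was an output gene of the circadian clock. Dbp, a transcription factor driven directly by the clock, averaged 6.53 ± 0.45 log2 units in treated and 2.83 ± 0.34 in control livers (SD, n = 3 each), a log2 difference of 3.71 ± 0.29 (SE), or at least 13.0-fold, since the control values lie near the lowest value. Per3, a member of the period family of clock repressors, was 6.23-fold higher, with a log2 difference of 2.64 ± 0.22 (SE). Its control livers were dim as well, averaging 3.61 log2 units, so that fold is less exact than the SE says. Me1, the cytosolic malic enzyme that supplies NADPH for fatty acid synthesis, had a log2 difference of -1.22 ± 0.14 (SE), and a second probe set gave -1.17. Tagln, an actin-binding protein of smooth muscle and activated stellate cells, stood 1.22 ± 0.13 (SE) higher on the log2 scale, with dim control values. None of these passed the test over all 10552 genes: limma gave an adjusted p of 0.106 for Dbp, Per3 and Tagln and of 0.113 for Me1, and the number of genes past an adjusted p of 0.05 was 0. At an unadjusted p under 0.05 limma counted 1546 genes, 930 higher and 616 lower in treated livers, where 528 would be expected by chance, and the 3 treated values lay apart from the 3 control values for 20.5% of genes against 10% by chance. With the Gapdh 3' to 5' gap, a sign of RNA quality, as a covariate the unadjusted count was 627. That gap separates treated from control livers, so the fit with it is less exact. With no filter on dim probe sets limma called 17 genes, with all 12 arrays in 1 fit 182, and without liver TCE replicate 3 it called 1.

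Other genes with the smallest p and no overlap between the groups also missed the threshold, with adjusted p from 0.106 to 0.126. Among those higher in treated livers were Ccdc191 (log2 difference 1.32 ± 0.12 SE, with control values near the lowest), Sphkap, which anchors protein kinase A (1.16 ± 0.12), and Mafg, a small Maf partner of Nrf2 (0.84 ± 0.07, although a second probe set of Mafg gave -0.10). LOC102549726, Nup214, Myo7b and Polr3e differed by 0.67, 0.64, 0.62 and 0.51, and 2 further probe sets of Nup214 gave -0.19 and 0.09. Among those lower were Phaf1 (-1.45 ± 0.16 SE), the sialyltransferase St6galnac3 (-1.12 ± 0.09, with treated values near the lowest), the sodium-proton exchanger Slc9a2 (-0.76 ± 0.08, with treated values near the lowest) and Uqcrc2, a core subunit of respiratory complex III (-0.59 ± 0.06, with -1.55 from a second probe set). Tmem37, Tmem160, Ten1, Pih1d1 and Fbxw5 differed by -0.70, -0.61, -0.60, -0.60 and -0.49.

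Of the 20 circadian clock genes measured in liver, 9 passed the threshold adjusted over the list alone, 5 of them higher and 4 lower after TCE. The higher ones were Dbp, Per3, Per2 (log2 difference 1.14 ± 0.25 SE, with -0.48 from a second probe set), Nr1d2 (1.01 ± 0.12) and the Dbp relative Tef (0.58 ± 0.09). The lower ones were Bmal1, the activator that pairs with Clock (-1.32 ± 0.20), Nfil3, a repressor that competes with Dbp (-1.07 ± 0.29), Cry1 (-0.96 ± 0.13) and Rora (-0.65 ± 0.20). Its members went both ways, and the list as a whole did not pass limma's camera test of a shift in one direction (adjusted p = 0.66). Per2 was lost from these calls without liver TCE replicate 2 or 3 or liver control replicate 2. Rora and Nfil3 were lost without any single liver array other than control replicate 1, whose omission left all 9 in place.

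**Figure D1:**
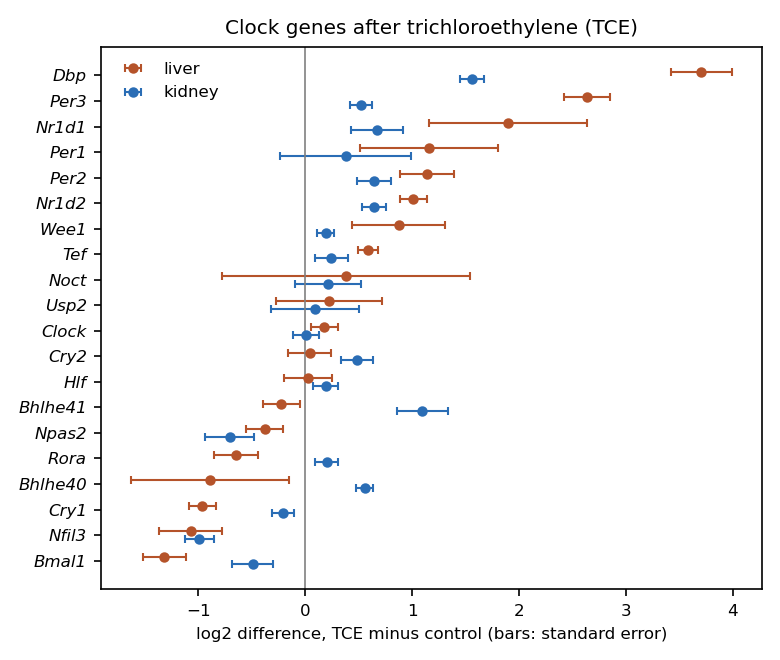
Log2 difference between TCE-treated and control rats (horizontal axis) for the 20 clock genes measured in liver and in kidney, with bars for the standard error of 3 against 3 arrays. Dbp lies highest in both tissues, at 3.71 in liver and 1.56 in kidney, and Bmal1 lies lowest in liver at -1.32.

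Genes of lipid, sugar and energy metabolism were lower as groups in treated livers. Of 19 fatty acid and triglyceride synthesis genes, 18 were lower, with a median log2 difference of -0.545 (camera adjusted p = 5e-05, adjusted p = 0.811 with an estimated correlation). Me1 and Pklr, the liver form of pyruvate kinase (-0.79 ± 0.16 SE), passed adjusted over the list alone. Of 30 respiratory chain genes, 24 were lower with a median of only -0.085 (camera adjusted p = 8.53e-05, adjusted p = 0.811 with an estimated correlation), and 5 passed adjusted over the list alone: Uqcrc2, Ndufb8 (-0.58), Atp5pb (-0.46), Sdhc (-0.43) and Cox6a1 (-0.31). Of 23 glucose metabolism genes, 19 were lower, with a median of -0.241 (camera adjusted p = 0.00233, adjusted p = 0.811 with an estimated correlation). Here Pklr, the glycolytic enzyme Eno1 (-0.46) and Pfkl, the liver phosphofructokinase (-0.46), passed adjusted over the list alone. Of 20 cholesterol synthesis genes 15 were lower and 0 passed over the list alone (camera adjusted p = 0.0489, adjusted p = 0.955 with an estimated correlation); Dhcr7 had -0.76, Pmvk -0.72 and Fdps -0.62, but Mvd 0.79. Of the calls over a list alone, Me1 and Uqcrc2 passed whichever liver array was left out. Pklr was lost from the fatty acid genes without any single array other than liver control replicate 3, and the 3 glucose genes without any other than liver TCE replicate 2. Cox6a1 and Sdhc were lost without any 1 array, Ndufb8 without any other than liver control replicate 3 and Atp5pb without any other than liver TCE replicate 3. Glucose genes no longer passed camera without liver control replicate 1 (adjusted p = 0.202), and cholesterol genes without liver TCE replicate 1 (0.221) or 3 (0.167) or liver control replicate 1 (0.395) or 3 (0.0867). The cholesterol call also ended with no filter on dim probe sets and with a replicate block. The same treated livers had a larger gap between the 3' and 5' Gapdh control probe sets, a sign of RNA quality, at 1.49 ± 0.254 log2 units against 0.814 ± 0.0398 (SD, n = 3 each, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The same gap for Actb, 5.33 ± 0.306 against 4.64 ± 0.521, did not separate the livers (exact permutation p = 0.3). With the Gapdh gap as a covariate the fatty acid list still passed camera. The glucose (median -0.117), respiratory chain (-0.0243) and cholesterol (-0.222) calls ended, in a fit with larger SE (for glucose a median SE of 0.515 against 0.202).

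Cell cycle genes and mesenchymal cell markers were higher as groups in treated livers. Of 28 cell cycle genes, 24 were higher, with a median log2 difference of 0.287 (camera adjusted p = 0.0163, adjusted p = 0.811 with an estimated correlation), and 0 passed adjusted over the list alone. Those with the smallest p were the proliferation antigen Mki67 (1.02 ± 0.23 SE, with dim control values), Ccnb2 (1.22 ± 0.40), the mitotic kinase Cdk1 (1.41 ± 0.50, with 2 control livers near the lowest value) and Ccna2 (0.68 ± 0.24). With the Gapdh 3' to 5' gap of each array as a covariate the cell cycle median was -0.0751 and that of the mesenchymal markers 0.427 (median SE 0.442, against 0.17 before), and neither list passed camera. The median SE of the cell cycle genes was 0.448 in that fit, against 0.203 before. Of 15 markers of fibroblasts, stellate cells and mesangial cells, 12 were higher, with a median of 0.332 (camera adjusted p = 0.0115, adjusted p = 0.811 with an estimated correlation), and Tagln, the smooth muscle myosin Myh11 (0.94 ± 0.14, with 1 control liver at the lowest value) and the stellate cell product Reln (0.47 ± 0.08) passed adjusted over the list alone. The cell cycle call ended without liver TCE replicate 1 (adjusted p = 0.142), liver control replicate 1 (0.0768) or liver control replicate 3 (0.0552), and with a stricter filter on dim probe sets, and the mesenchymal call without liver TCE replicate 2 (0.0571) or liver control replicate 3 (0.0936). These groups too moved beside the larger Gapdh gap of the treated livers (difference 0.676 log2 units). For the liver list calls together, 2 of 10 splits of the 6 arrays, the real one included, gave at least the real 6. The highest other count was 8.

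**Figure D2:**
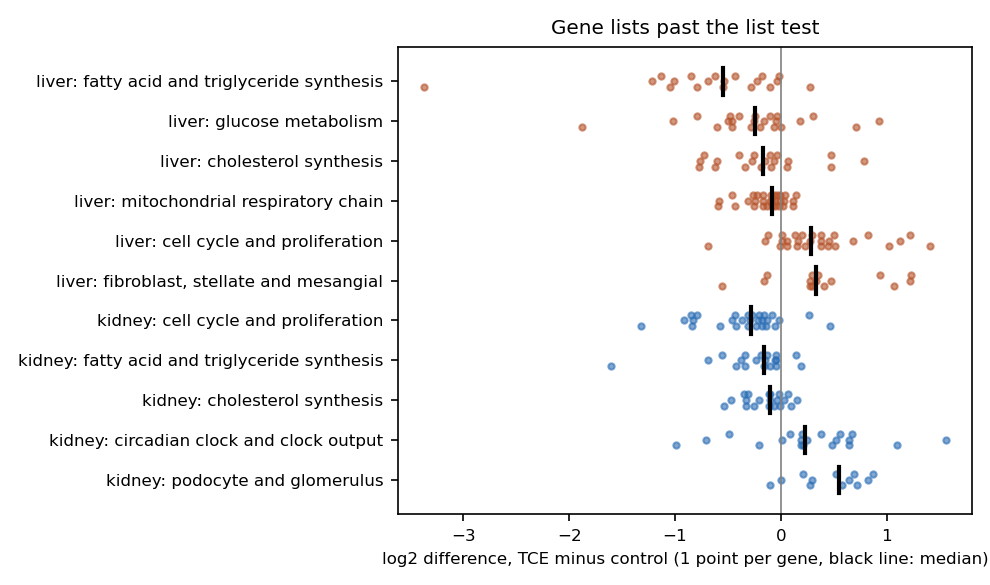
Log2 difference between TCE-treated and control rats for every measured gene of the 11 lists past camera, with 1 point per gene and a black line at the list's median. Median lines run from -0.545 for fatty acid synthesis in liver to 0.547 for podocyte markers in kidney.

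Single members of other lists passed in liver only when adjusted over the list alone. They were Mt1, a metal-binding metallothionein (log2 difference 1.5 ± 0.30 SE), the basolateral transporter Slc13a3 (0.65), the intermediate filament Krt18 (0.62), the urea cycle enzyme Asl (0.49), Slc4a1 (-1.06), the asialoglycoprotein receptor subunit Asgr2 (-0.60), Cyp2c22 (-0.58), Slc17a1 (-0.53) and the lipid droplet protein Hsd17b13 (-0.47). Me1 also passed among the NRF2 and oxidative stress genes. Slc4a1 is also among the erythroid markers, a list that passed camera in liver with no filter on dim probe sets. Over all lists in liver, 35 gene and list pairs passed in this way; without 1 array at a time between 15 (without liver control replicate 2) and 23 (without liver control replicate 1) of the 35 still passed. Cyp2c22 was lost without any 1 array, Asgr2 without any other than liver TCE replicate 3, and Hsd17b13 without any other than liver control replicate 1. Mt1 and Krt18 were lost without liver TCE replicate 1 or 2 or liver control replicate 2 or 3, and Asl without liver TCE replicate 2 or 3 or liver control replicate 2 or 3. Slc13a3 passed in 3 lists and was lost from all 3 without liver control replicate 2 or 3, Slc17a1 was lost without liver control replicate 1 or 3, and Slc4a1 without liver control replicate 3.

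The genes named in the study's title, those of vitamin B12-dependent methionine salvage, did not pass the test in liver. Mtr, the methionine synthase that uses vitamin B12, had a log2 difference of 0.29 ± 0.20 (SE, 3 against 3 arrays; limma adjusted p = 0.546), and Mtrr, which reactivates it, 0.05 ± 0.07 (0.764). The Mtr probe set was dim, at 4.01 log2 units in treated and 3.72 in control livers, near the array medians of 3.51 to 3.54. That it missed the threshold therefore says little about Mtr. Mmut, the other B12-dependent enzyme, had 0.09 ± 0.18 (0.857), but its further probe sets gave -0.17 and -0.53. Mat1a, which makes S-adenosylmethionine, had -0.07 ± 0.12, Gnmt, which consumes it, -0.21 ± 0.27, and Ahcy, which hydrolyses S-adenosylhomocysteine, -0.30 ± 0.13. Bhmt, which remethylates homocysteine without B12, had -0.66 ± 0.35, and the transsulfuration enzymes Cbs and Cth -0.20 ± 0.10 and -0.35 ± 0.23. Without liver control replicate 1 the difference was 0.10 for Mtr in liver, -0.18 for Ahcy in liver, -0.26 for Bhmt in liver and -0.16 for Cth in liver, and without liver control replicate 2 it was 0.49 for Mtr in liver. Mtrr in liver had 0.01 without liver TCE replicate 3 and 0.09 without liver TCE replicate 2. Without liver control replicate 1 the sign turned for Mat1a (0.04) and Gnmt (0.08), and for Mmut without liver TCE replicate 1 (-0.06) or liver control replicate 2 (-0.04). Of the 24 genes of methionine and B12 handling, 15 were lower and 9 higher. The list did not pass camera (adjusted p = 0.112), and 0 of its members passed in limma over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05.

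Folate and formate genes of liver did not pass over all genes either. Formate enters the folate pool through Mthfd1 (log2 difference -0.20 ± 0.13 SE) and leaves it through Aldh1l1 (-0.30 ± 0.14). Ftcd, of histidine breakdown, had -0.18 ± 0.14 and Shmt1, the cytosolic serine hydroxymethyltransferase, 0.16 ± 0.09. Without liver control replicate 1 the difference was -0.06 for Ftcd in liver, -0.11 for Mthfd1 in liver and 0.10 for Shmt1 in liver. Of 30 genes 18 were lower and 12 higher, and the list did not pass camera (adjusted p = 0.332). Adjusted over the list alone, 1 passed: Gldc, of glycine cleavage, at -0.74 ± 0.10 (adjusted p = 0.0144), although its second probe set gave 0.28, and it was lost without liver TCE replicate 2 or 3 or liver control replicate 1. None of the 13 preset methionine and folate enzymes passed limma's test over all genes in liver, with adjusted p from 0.375 for Ahcy to 0.857 for Mmut.

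**Figure D3:**
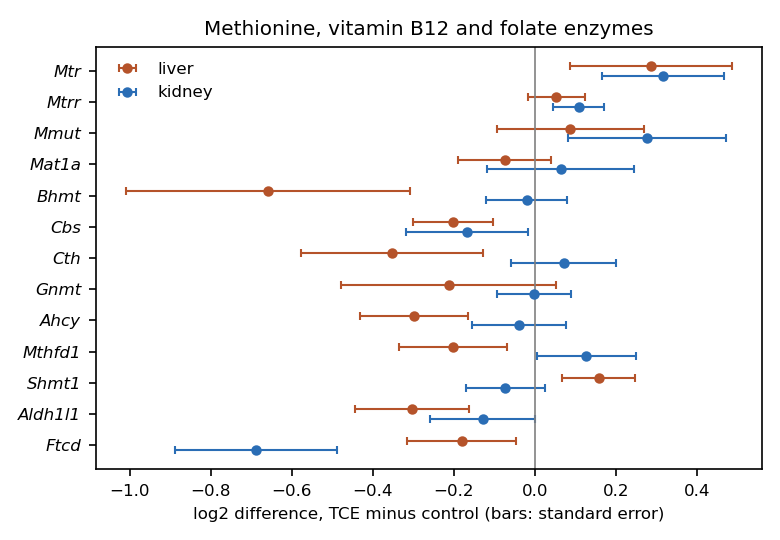
Log2 difference between TCE-treated and control rats for 13 enzymes of methionine, vitamin B12 and folate metabolism in liver and kidney, with bars for the standard error of 3 against 3 arrays. Values run from -0.69 for Ftcd in kidney to 0.32 for Mtr in kidney, and none passed limma's test over all genes.

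In renal cortex the same clock output gene, Dbp, led the comparison, at 10.22 ± 0.05 log2 units in treated and 8.66 ± 0.20 in control kidneys (SD, n = 3 each), or 2.95-fold higher (log2 difference 1.56 ± 0.11 SE). Nfil3, which binds the same promoter elements as Dbp and represses them, had -0.99 ± 0.14. None of the genes passed over all 10563 tested: limma's adjusted p was 0.156 for Dbp, the smallest, and 0.188 for Nfil3, and the number past 0.05 was 0. At an unadjusted p under 0.05 limma counted 1566 genes, 799 higher and 767 lower, against 528 expected by chance, and 20.1% of genes separated the groups without overlap against 10% by chance. The unadjusted count was 919 without kidney TCE replicate 1, 2099 without kidney TCE replicate 2 and 2298 with array weights. Limma called 2 genes with no filter on dim probe sets, 1 with a stricter filter, 1 with trend and robust variances and 20 with all 12 arrays in 1 fit.

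The other genes with the smallest p in kidney had adjusted p of 0.184 to 0.188. Higher in treated kidneys were Cttnbp2 (log2 difference 0.98 ± 0.12 SE), Opcml (0.91 ± 0.12, with control values near the lowest), Ankrd45 (0.87 ± 0.09), the carboxylesterase Ces1e (0.78 ± 0.10, with control values near the lowest), Brd10 (0.64 ± 0.07), Manf, a secreted protein of endoplasmic reticulum stress (0.59 ± 0.08), the endothelial matrix protein Mmrn2 (0.59 ± 0.08), Id1, an inhibitor of basic helix-loop-helix factors (0.57 ± 0.06), and Impact (0.49 ± 0.06). Lower were Hmmr, a mitotic spindle and hyaluronan receptor protein (-0.93 ± 0.08, with 1 treated array at the lowest value), Ttc14 (-0.88 ± 0.07), Cuedc1 (-0.85 ± 0.12), Ap4b1 (-0.80 ± 0.09), Bmf, a pro-apoptotic Bcl2 relative (-0.61 ± 0.07), Nbeal2 (-0.56 ± 0.07), the kinase Rps6ka2 (-0.50 ± 0.06, with treated values near a repeated low value), Sppl3 (-0.44 ± 0.06) and Tbc1d16 (-0.43 ± 0.06).

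Of 12 podocyte and glomerulus markers measured in kidney, 11 were higher, with a median log2 difference of 0.547 (camera adjusted p = 8.53e-05, adjusted p = 0.585 with an estimated correlation). A second list of 22 podocyte genes, drawn up after that call was seen, had a median of 0.0047, with 12 higher, 10 lower and 0 past over the list alone. Of the 12 markers, 6 passed adjusted over the list alone: the slit diaphragm protein Nphs1 (0.87 ± 0.15 SE), the guidance receptor Robo2 (0.83 ± 0.14), the receptor phosphatase Ptpro (0.69 ± 0.11), the surface sialoprotein Podxl (0.65 ± 0.15), Dach1 (0.58) and the transcription factor Wt1 (0.52). The list passed camera without any single kidney array, with the highest adjusted p at 0.00292, but Dach1 was lost without any single array other than kidney TCE replicate 3, Wt1 without any other than kidney control replicate 2, and Podxl without kidney control replicate 1 or 2. Of 28 cell cycle genes, 26 were lower, with a median of -0.282 (camera adjusted p = 7.43e-04, adjusted p = 0.811 with an estimated correlation). Mki67 had -1.32 ± 0.30 and the replication helicase subunits Mcm6 and Mcm7 -0.84 ± 0.22 and -0.21 ± 0.07, while Pcna had 0.27 ± 0.08; 0 passed adjusted over the list alone. The cell cycle call ended with a stricter filter on dim probe sets. Beside these groups the Actb gap separated treated from control kidneys (difference -0.173), and hepatocyte markers had a median of -0.742. A limit on all kidney list calls, here and below, is that other splits of the same 6 arrays gave as many. Of 10 splits, the real one included, 6 gave at least the real 5 lists past camera, with 8 the highest other.

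Of 20 clock genes in kidney, 16 were higher (camera adjusted p = 0.00776, adjusted p = 0.811 with an estimated correlation; 0.0629 without kidney TCE replicate 2). Adjusted over the list alone 7 passed as higher, Dbp, Bhlhe41 (log2 difference 1.09 ± 0.24 SE), Nr1d2 (0.64 ± 0.11), Per2 (0.64 ± 0.16), Bhlhe40 (0.56 ± 0.08), Per3 (0.52 ± 0.10) and Cry2 (0.48 ± 0.15), and 1, Nfil3, as lower. Cry2 was lost without any single kidney array other than TCE replicate 1. Per2 was lost without kidney TCE replicate 2 or 3 or kidney control replicate 2 or 3, and Bhlhe41 without TCE replicate 2 or 3 or control replicate 2. Fatty acid and triglyceride synthesis genes were lower in 17 of 19 cases (camera adjusted p = 0.0274, adjusted p = 0.811 with an estimated correlation), with Pklr at -0.56, Acaca at -0.42, Dgat2 at -0.34 (0.06 from a second probe set) and Fasn at -0.24. Cholesterol synthesis genes were lower in 16 of 20 (camera adjusted p = 0.0489, adjusted p = 0.811 with an estimated correlation), with Mvd at -0.54, Pmvk at -0.35, Dhcr7 at -0.32 and Lss at -0.26 (0.22 from a second probe set). In both of these lists 0 members passed adjusted over the list alone. The fatty acid call ended without kidney TCE replicate 1 (adjusted p = 0.109) or kidney control replicate 2 (0.142), and the cholesterol call without kidney TCE replicate 2 (0.0736) or 3 (0.145) or kidney control replicate 1 (0.149) or 2 (0.0725), and with a stricter filter. Liver transcripts differed between kidney arrays beside these groups: Alb, the main liver secretory transcript, was at 9.89, 12.8 and 7.84 in kidney control replicates 1, 2 and 3 and at 11, 4.36 and 6.31 in TCE replicates 1, 2 and 3, so it did not simply follow treatment, against 16.3 in control liver. As a list, 11 of 13 hepatocyte markers were lower in treated kidneys (median -0.742, camera adjusted p = 0.0867). That list passed camera with each array centred on its median. It also passed without kidney TCE replicate 1, kidney control replicate 1 or kidney control replicate 3. The Actb gap between 3' and 5' control probe sets was smaller in all 3 treated kidneys (4.31 against 4.48, exact permutation p = 0.1), and the Gapdh gap was 0.655 against 0.971 (exact permutation p = 0.2).

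Glucose metabolism genes in kidney did not pass camera (adjusted p = 0.188), but 6 passed adjusted over the list alone. They were Igfbp2 (log2 difference 0.79 ± 0.17 SE), higher, and Sds (-0.93 ± 0.19), Igfbp1 (-0.60 ± 0.16), Pklr, Pfkl (-0.40 ± 0.08) and Foxo1 (-0.35 ± 0.08), lower. None of these 6 passed without kidney TCE replicate 1 or 3 or kidney control replicate 1. Single members of other lists that passed in this way were the tissue kallikrein Klk1 (0.81), the macrophage receptor Adgre1 (0.64), the chaperone Dnajb9 (0.51), Azin1 (0.31), Hsd17b13 (-0.77) and Atf5 (-0.47). Azin1, Atf5 and Dnajb9 were lost without any single kidney array other than TCE replicate 2, as was Hsd17b13. Adgre1 was lost without kidney TCE replicate 1 or 3 or kidney control replicate 3, and Klk1 without kidney TCE replicate 1 or 2 or kidney control replicate 3. Of 27 such gene and list pairs, between 11 (without kidney TCE replicate 3) and 17 (without kidney TCE replicate 2) still passed when 1 array was left out.

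Methionine and folate genes in kidney did not pass the test. The Mtr probe set was dim here too, at 4.61 log2 units in treated and 4.29 in control kidneys. Mtr had a log2 difference of 0.32 ± 0.15 (SE), Mmut 0.28 ± 0.19, Mtrr 0.11 ± 0.06 (-0.28 from a second probe set), Cth 0.07 ± 0.13, Mat1a, whose kidney values lie near the lowest value, 0.06 ± 0.18, Gnmt -0.00 ± 0.09, Bhmt -0.02 ± 0.10, Ahcy -0.04 ± 0.12 and Cbs -0.17 ± 0.15. The folate enzymes Mthfd1, Shmt1 and Aldh1l1 had 0.13 ± 0.12, -0.07 ± 0.10 and -0.13 ± 0.13. Ftcd had -0.69 ± 0.20, all 3 treated values below all 3 control values, and the smallest adjusted p of these genes in kidney (limma adjusted p = 0.264). Of the 13 it alone kept its difference within 1.5 times whichever kidney array was left out. Of 26 methionine and B12 genes 15 were higher and 11 lower (camera adjusted p = 0.716), and of 29 folate genes 16 and 13 (0.961). In limma 0 members of either list passed over all genes or adjusted over the list alone.

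**Figure D4:**
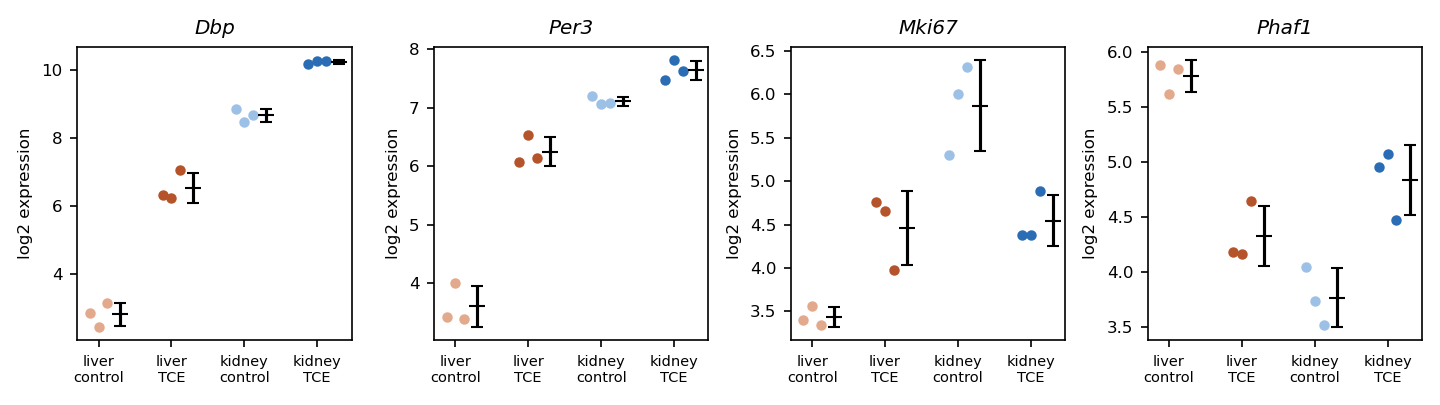
Log2 expression of Dbp, Per3, Mki67 and Phaf1 on each of the 12 arrays, with bars for the mean and SD of the 3 arrays of each group. Treatment differences had opposite signs in liver and kidney for Mki67 (1.02 and -1.32, but -0.05 for Mki67 in liver in a less exact fit with the Gapdh gap as a covariate) and for Phaf1 (-1.45 and 1.07).

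The treatment effect differed between liver and kidney for 57 of 10652 genes (limma, adjusted p under 0.05), 20 with the more positive effect in liver and 37 with the more positive effect in kidney. Klk1c4, a tissue kallikrein family member, averaged 6.41 in treated and 2.76 in control kidneys and sat at 1 repeated low value in all 3 treated livers, a difference of effects of -3.86 ± 0.63 log2 units (SE; adjusted p = 0.0342). Mki67 had 1.02 in liver and -1.32 in kidney, so its effects differed by 2.35 ± 0.39 (0.0364), but with the Gapdh gap as a covariate Mki67 in liver had -0.05. The covariate fit is less exact, with a median SE of liver cell cycle genes of 0.448 against 0.203 before. The clock genes Dbp and Per3 were higher in both tissues and by more in liver, by 2.14 ± 0.32 (0.0214) and 2.11 ± 0.25 (0.0142). Control livers were dim for Dbp, Per3 and Mki67. The value of Dbp is therefore a lower bound, and those of Per3 and Mki67 are less exact than the SE says. Phaf1 differed by -2.52 ± 0.28 (0.0142), with -1.45 in liver and 1.07 in kidney. Pdk1, the kinase that restrains pyruvate dehydrogenase, differed by -1.79 ± 0.25 (0.0202) and Msra, which repairs oxidised methionine in proteins, by -1.58 ± 0.20 (0.0162), each lower in treated liver and higher in treated kidney. Rgs12, a regulator of G-protein signalling, differed by -1.56 ± 0.28 (0.0481), but its kidney control values were all at 1 repeated low value. The fit treats the 12 arrays as independent although both tissues came from the same rats, and with the replicate number as a block the count was 0. The count rested on single kidney arrays: it was 0 without kidney TCE replicate 1, 2 without kidney control replicate 1 and 18 without kidney control replicate 3. It was 32 without kidney TCE replicate 3 and 108 without kidney TCE replicate 2. Leaving out liver TCE replicate 1, 2 or 3 gave 30, 29 or 93 and leaving out liver control replicate 1, 2 or 3 gave 35, 36 or 29. The Gapdh gap, TCE minus control, was 0.676 log2 units in liver and -0.316 in kidney. RNA quality is therefore not separated from the differences of effects.

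As a list, cell cycle genes had the more positive effect in liver, with a median difference of effects of 0.49 (camera adjusted p = 2.67e-04, adjusted p = 0.465 with an estimated correlation). Respiratory chain genes had the more negative effect in liver, with a median of -0.0996 (camera adjusted p = 0.0093, adjusted p = 0.891 with an estimated correlation); that call ended without liver control replicate 1 (0.0764). These differences stand beside the larger Gapdh gap of the treated livers, and with that gap as a covariate the liver medians were -0.0751 for cell cycle genes (0.287 before) and -0.0243 for the respiratory chain (-0.085 before). Their median SE rose from 0.203 to 0.448 and from 0.0807 to 0.208. Uqcrc2 and Ndufb8 were among the 57 genes, with differences of -0.79 and -1.0.

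**Figure D5:**
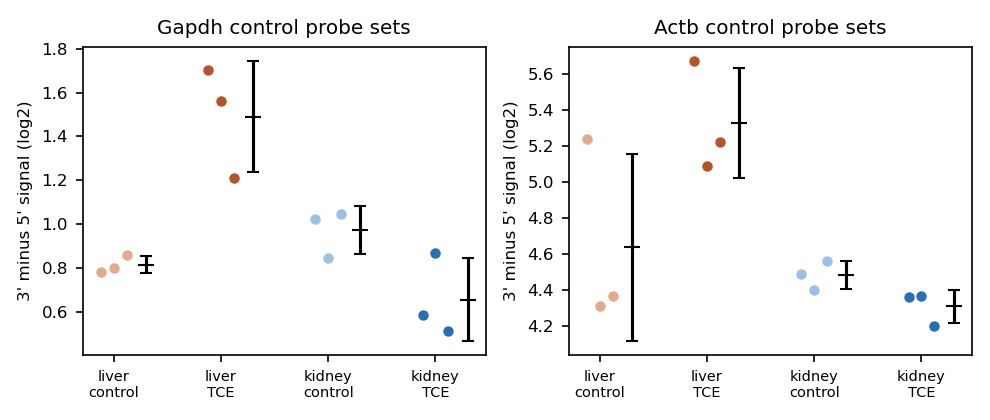
Difference between the 3' and 5' control probe sets of Gapdh and of Actb (log2) on each of the 12 arrays, with bars for the mean and SD of 3 arrays per group. The 3 treated livers lie at or above 1.21 for Gapdh and the 3 control livers at or below 0.859.

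Control liver against control kidney gave the baseline levels of the same pathways. Mat1a averaged 14 log2 units in control liver and 2.58 in control kidney, which is close to the lowest value, so the log2 difference of 11.42 is a lower bound. Bhmt was higher in liver by 6.84 ± 0.34 (SE, n = 3 each), Gnmt by 4.34 ± 0.27, Ftcd by 4.18 ± 0.14, Ahcy by 1.85 ± 0.16, Cbs by 1.14 ± 0.12, Cth by 1.09 ± 0.23, Aldh1l1 by 0.96 ± 0.14, Shmt1 by 0.37 ± 0.09 and Mtrr by 0.27 ± 0.07, each past limma's threshold (largest adjusted p = 0.0204, of Mtrr). Mtr had -0.57 ± 0.20 (adjusted p = 0.0443), which missed the threshold without any single array except liver control replicate 2 and was -0.11, not past the threshold, after quantile normalization. Mmut (0.37 ± 0.20) and Mthfd1 (-0.22 ± 0.14, but 0.18 with each array centred on its median) did not pass. The tissue labels were matched by Apoa1, a liver apolipoprotein, at 12.48, Alb at 6.14, and the tubule genes Umod at -12.66, Slc12a1 at -12.02 and Slc34a1 at -11.80; Umod was at 1 repeated low value in all 3 control livers, Slc12a1 was at the lowest value in 1, and Apoa1 averaged 2.34 in control kidney, so the differences of Umod, Slc12a1 and Apoa1 too are lower bounds. In all, limma called 7309 of 10654 genes, 3162 higher and 4147 lower in liver. That split depends on scaling, since quantile normalization gave 3936 higher and 3806 lower and centring on medians 5228 higher and 2844 lower, with the median difference of all genes at -0.0953 as deposited, 0.0257 after quantile normalization and 0.31 after centring.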

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

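Chosen only after the result was seen were the tests of clock gene phase, of clock genes against RNA quality, of hepatocyte markers, of gene lists on the difference of effects, and the fit with the Gapdh gap as a covariate. The treatment effect differed between liver and kidney for 57 genes by limma's interaction term. Of 100 relabelings of treatment within each tissue 1, the real one, reached that count, with 25 as the highest of the others. For arrays taken as independent, this argues at the 0.05 level against treatment labels that make no difference in either tissue. Relabeling removes the effect of each tissue as well as their difference. It therefore does not by itself show that the effects differ between tissues. RNA quality also moved in opposite directions: the Gapdh gap, TCE minus control, was 0.676 log2 units in liver and -0.316 in kidney. RNA quality is thus not separated from the difference of effects, and a covariate for it was fitted in liver only. Both tissues came from the same rats, and with the replicate number as a block 0 of the 57 passed, so that limit stays. The block also leaves fewer residual degrees of freedom, so this fall does not by itself show dependence between the tissues. The same count was 0 without kidney TCE replicate 1, 2 without kidney control replicate 1, 18 without kidney control replicate 3, 32 without kidney TCE replicate 3 and 61 and 108 without kidney control replicate 2 and kidney TCE replicate 2. It was 30, 29 and 93 without liver TCE replicate 1, 2 and 3, and 35, 36 and 29 without liver control replicate 1, 2 and 3. The 8 genes of largest difference, liver effect minus kidney effect in log2 units, were Klk1c4 (-3.86), Phaf1 (-2.52), Mki67 (2.35), Dbp (2.14, a lower bound), Per3 (2.11), Pdk1 (-1.79), Msra (-1.58) and Rgs12 (-1.56); without kidney TCE replicate 1, 0 of the 8 passed, with adjusted p from 0.0557 to 0.114. The lists of cell cycle genes (camera adjusted p = 2.67e-04) and of respiratory chain genes (0.0093, and 0.0764 without liver control replicate 1) also had effects that differed between the tissues, and 0 lists did with an estimated correlation.

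Clock genes were shifted in both tissues, and a difference in RNA quality between the groups, a common technical cause, is argued against by the kidney. There 8 clock genes passed adjusted over the list alone although the treated kidneys had the smaller Gapdh 3' to 5' gap, by -0.316 log2 units (exact permutation p = 0.2), and the smaller Actb gap, by -0.173 (p = 0.1, all 3 treated below all 3 controls), the opposite direction to liver. This test was chosen with the kidney values already seen, and the kidneys were not matched in RNA quality. It bears on a quality difference acting alike in both tissues, and not on each tissue alone. Genes in phase with Dbp minus genes in antiphase were higher in treated rats by 1.93 ± 0.233 in liver and 1.08 ± 0.245 in kidney (SE, n = 3 each, exact permutation p = 0.1 in each, the smallest possible). The smaller of these, 1.08, is what both a difference in the time of day at which the groups were killed and an effect of TCE on the clock would give, and the 2 cannot be told apart because the hour of killing of each rat is not given in the sources used here. A shift in killing time is therefore a candidate explanation for Dbp, Per3 and the other shifted clock genes, and a treatment effect remains another. The hour of killing belongs to the whole rat, and its bearing on genes outside the clock list was not tested.

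Fatty acid, glucose and respiratory chain lists were lower in treated livers by camera at its preset correlation only (adjusted p = 0.811 for each with an estimated correlation), and the gap between the 3' and 5' Gapdh control probe sets was larger there by 0.676 log2 units, a signal outside the gene comparisons that separated all 3 treated from all 3 control livers, while the Actb gap did not (exact permutation p = 0.3). A loss of hepatocytes as large as the fatty acid and glucose shifts is argued against. Hepatocyte markers had a median shift of -0.0334, with a median absolute deviation of 0.0607, against -0.545 and -0.241. Of the 15 markers 11 were lower, with Asgr2 at -0.60. Some lie near the top of the scale, such as Alb at 16.3 in control liver, and whether a small loss shows there was not tested. For the respiratory chain, with a median of -0.085, the same marker median leaves the question open. RNA quality could not be separated from treatment: the shift that each gene's slope on the Gapdh gap within groups predicts had a Spearman rho of 0.199 with its treatment effect across the 71 genes of the lists, which are not independent replicates, and 0.189 across all genes tested; it was 0.45 for the glucose and 0.353 for the respiratory chain genes, above the 0.3 set beforehand as a sign of that cause for the lists together. With the gap as a covariate the fatty acid median was -0.484 (-0.545 before, with a median SE of 0.424 against 0.224). The camera p of that list was 4.59e-05 at the preset correlation. The glucose and respiratory chain medians became -0.117 and -0.0243 and both calls ended. Their median SE rose too, from 0.202 to 0.515 and from 0.0807 to 0.208. The gap separates treated from control livers, so this fit cannot tell calls lost to RNA quality from calls lost to lower precision. Lower RNA quality in the treated livers may account for part of the pattern, least for the fatty acid genes (rho 0.0386, with a predicted median of 0.0852 against the observed -0.545). A treatment effect on hepatic metabolism remains open. So does a difference in killing time, which was not tested for these lists.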

How the results depend on the processing

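Tests chosen only after the results were seen were the Gapdh gap as a covariate, genes with a repeated value left out, lists without markers, gene lists on the difference of effects, and list members recomputed without each array. Dim genes are a limit: Klk1c4 and Rgs12 each have 1 group at a repeated low value, and Dbp, St6galnac3, Ccdc191, Cdk1, Myh11 and Slc9a2 in liver and Ces1e, Opcml, Rps6ka2 and Hmmr in kidney have a group near the lowest or a repeated low value, so their differences are less exact than the SE says. Mtr in both tissues, Ccna2 in liver, Hsd17b13 in kidney, and Per3, Mki67 and Tagln in control livers were dim as well. In liver limma's count of 0 (1546 at an unadjusted p under 0.05) became 17 with no filter, 182 with all 12 arrays in the fit, and 0 to 1 without single arrays (1 without liver TCE replicate 3). In kidney the count of 0 (1566 at an unadjusted p under 0.05) became 2 with no filter, 1 with a stricter filter, 1 with trend and robust variances, 20 with all 12 arrays, and 0 without each array. An adjusted p under 0.1, or a 1.5-fold minimum, gave 0 in each tissue. All 12 arrays add genes' spread from the other tissue and residual degrees of freedom; for the other settings the cause was not tested. The 57 genes of the difference in effect became 198 over all probe sets, which tests more units, 123 with array weights, and 0 to 108 without single arrays (0 without kidney TCE replicate 1); the count was 54 when genes with a repeated value were left out. Control liver against kidney gave 11514 calls over all probe sets, and 6622 to 7009 genes without single arrays. The 6 liver lists became 0 with an estimated correlation, 3 without liver control replicate 1 or 3 (range 3 to 6 without single arrays), 5 with a stricter filter (the cell cycle call ended) and 5 without marker lists. With the Gapdh covariate 4 liver lists passed, of which 1, fatty acid synthesis, was among the 6; the other 5 were lost and the PPAR-alpha, acute phase and glucocorticoid lists passed instead. The 5 kidney lists became 0 with an estimated correlation, 3 with a stricter filter (the cell cycle and cholesterol calls ended), 3 without kidney TCE replicate 2 (range 3 to 7) and 4 without marker lists.

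Whether equal replicate numbers mark the same rat is not shown by the data: deviations from group means of same-numbered arrays correlated at -0.0947 to 0.08 across groups, under 0.1 for every pair. That range includes treated with control arrays, which are different rats. Across liver and kidney, control numbers correlated best with their own in 3 of 3 cases and treated numbers in 1 of 3. This is a weak hint that some numbers may pair. Treated and control kidneys of unlike number, which are different rats, correlated at up to 0.208. With a replicate block, 0 genes had a different effect between tissues, 0 were called in liver and 0 in kidney, 6993 between control tissues, and 5 lists in each tissue (in liver cholesterol synthesis was lost).

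Signs reversed as follows; the cause was not tested except where the averaged probe sets differ in sign. With the mean of all probe sets Mmut in liver had -0.21 and Mtrr in kidney -0.0862. The Gapdh covariate gave Mmut in liver -0.31, Mki67 in liver -0.0506, Ccnb2 in liver -0.27 and Ccna2 in liver -0.12. The fit with it is less exact, since the gap separates treated from control livers. Array weights gave Mat1a in kidney -0.0443, and centring on medians gave Gnmt in kidney 0.0103 and Mthfd1 in control liver against control kidney 0.18. Without single arrays the ranges were -0.055 to 0.197 for Mmut in liver, -0.144 to 0.0428 for Mat1a in liver and -0.414 to 0.0815 for Gnmt in liver. They were -0.137 to 0.192 for Mat1a in kidney, -0.0936 to 0.0389 for Bhmt in kidney, -0.0284 to 0.201 for Cth in kidney, -0.0456 to 0.0841 for Gnmt in kidney, -0.148 to 0.0197 for Ahcy in kidney and -0.123 to 0.0143 for Shmt1 in kidney. None of these values was past the threshold. The fit of all 12 arrays put 32 further results for named genes past the threshold.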

Other observations

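The comparison of liver with kidney effects gene by gene, and the choice of the examples given for it and of Havcr1, were made only after the effects had been seen. In liver, 38 target genes of PPAR-alpha, the receptor for fatty acids that chlorinated acetates activate in rodents, did not pass as a group (18 higher, median log2 difference -0.0219, camera adjusted p = 0.218), and 0 passed in limma adjusted over the list alone. Enzymes of TCE metabolism (20 genes, median -0.0827, adjusted p = 0.435), xenobiotic P450s and their regulators (29 genes, -0.0544, 0.205), NRF2 and oxidative stress genes (28 genes, 0.043, 0.707), p53 and DNA damage genes (17 genes, 0.0346, 0.66) and acute phase and inflammation genes (30 genes, 0.0881, 0.82) did not pass either. Bile acid genes were higher in 15 of 19 cases without passing (median 0.0962, adjusted p = 0.245). With the Gapdh gap as a covariate, chosen after the data were seen, the PPAR-alpha, acute phase and glucocorticoid lists did pass camera at its preset correlation. Kupffer cell (median -0.0117), endothelial (0.0646) and lymphocyte (-0.16) markers in liver had adjusted p of 0.707, 0.868 and 0.674.

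In kidney, 29 kidney injury genes did not pass (11 higher, median -0.095, camera adjusted p = 0.66), and Havcr1, a marker of proximal tubule injury, had a log2 difference of -2.52 ± 0.79 (SE; adjusted p = 0.517 over the list alone). Markers of the proximal tubule's first segments (median 0.0809, adjusted p = 0.332), thick ascending limb (0.0972, 0.66) and intercalated cells (0.202, 0.112) did not pass, nor did the genes of acid-base and anion transport (0.0344, 0.469) or macrophage markers (0.11, 0.205). Hepatocyte markers had a median of -0.742 (adjusted p = 0.0867) on kidney arrays, where Ttr was at 8.21, Fgb at 6.67 and Cps1 at 6.15 in kidney control replicate 2, and Apoa1 at 2.44. Effects in liver and kidney had a Pearson r of -0.0191 and a Spearman rho of -0.0684 across 10180 genes, which are not independent replicates. At an unadjusted p under 0.05 in both tissues, 68 genes were higher in both (69.4 expected from independent lists), 50 lower in both (43.1) and 66 higher in liver and lower in kidney (65.6), but 77 were lower in liver and higher in kidney, where 45.5 were expected; no test was made of that excess. Among the 77 were Msra, Prkacb, Ndufb8 and Nck1. The Gapdh 3' to 5' gap, TCE minus control, also had opposite signs, at 0.676 in liver and -0.316 in kidney. Its bearing on these 77 genes was not tested.

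The first list of podocyte and glomerulus markers was higher in treated kidneys (median 0.547) by camera at its preset correlation only (adjusted p = 0.585 with an estimated correlation). For it 2 technical explanations were tested, each with a bound set before its result was seen. A single deviating array is argued against, since without kidney control replicate 2, the array with the highest liver transcripts, the list kept a median of 0.573 and a camera p of 6.37e-05 at the preset correlation. More glomerular tissue in the treated samples stays open: a second list of 22 podocyte genes had a median of 0.0047, with 12 higher against 10 lower, which lies under the bound of 0.05 set against that explanation but by less than its SE of 0.0635, and 15 further glomerular endothelial genes, 3 of them also in the endothelial marker list, had a median of 0.109. The SE of 0.0635 is that of the median across the 22 genes, taken as independent, and does not measure the spread between rats. The bound itself did not include this SE, and the median of the second podocyte list met the bound. That list thus gave no sign of more glomeruli, without excluding them. A treatment effect on podocytes was not tested apart from glomerular sampling.

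Other splits of the same arrays bear on the counts. The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. For the genes called by limma the share says nothing, because any split calls at least the real count of 0. It was 10 of 10 in liver, where the highest other count was 0, while at an unadjusted p under 0.05 the real split gave 1546 genes and the highest other 622. In kidney it was also 10 of 10, with 3 as the highest other count, and 1566 against 924 at an unadjusted p under 0.05. For gene lists in liver 2 of 10 splits gave at least the real 6, with 8 the highest other, and in kidney 6 of 10 gave at least the real 5, also with 8 the highest other. Control liver against control kidney gave 7309 genes in 1 of 10 splits, the real one, and 0 as the highest other.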
